A study of Mus musculus with 6 samples.

How the data were processed

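Gene expression was measured in 6 RNA sequencing libraries of mouse bone marrow-derived macrophages, 1 for each of 2 genotypes (WT and Setd2 KO) at 3 times (0, 12 and 24 h with LPS). Per the labels' protocols, marrow of C57BL/6 mice aged 8 weeks was cultured with M-CSF for 5 days, LPS was given at 100 ng/ml, and total RNA was extracted with TRIzol and sequenced on the BGISEQ-500 platform. The labels do not say whether libraries share an animal, a culture or a sequencing run, and they do not describe the Setd2 allele. The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the mapped total) as computed by the authors, per the file headers, with 2 decimals. Per the submitters' processing notes, the values were made with Bowtie2, RSEM and the genome build GRCm38; no versions or settings are given. Counts were not used here, and the table does not record depth. Depth was estimated for each library from the steps that whole reads leave in the FPKM of weakly expressed genes, with an assumed read length of 50. The estimates were 21840000, 21850000 and 22120000 mapped reads for WT at 0, 12 and 24 h, and 22060000, 22000000 and 22580000 for KO. The fit of the steps scored 0.446 to 0.521, against 0.0542 to 0.181 with transcript lengths shuffled. Column totals of FPKM lay between 459001 and 582083.

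The table had 17905 rows. The 1 that names no gene was left out, and 17904 genes were used. Gene symbols that had become dates (25) were restored from their gene IDs. The KO 0 h column held 2 cells that are not numbers, for Cd36 and Cers5, which were read as missing. Coordinates were taken from the RefSeq annotation of GRCm38 for 17863 genes, and transcript lengths and GC content from GENCODE M21, with a length for 11436 (99.0%) of the measured genes. A gene counted as measured if it reached 1 FPKM in at least 1 library, which 11549 did.

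With 1 library per group no single comparison has a test or a p-value across genes; the only p-values come from limma's additive fit over the 3 times, an alternative. Each comparison is a difference of log2(FPKM + 1), and a measured gene was called at a size of 1 (2-fold) or more. The comparisons were KO against WT at each time, LPS against 0 h in each genotype at 12 and 24 h, 24 h against 12 h in each genotype, and the difference of the LPS responses (KO minus WT). A gene was called at all 3 times when it was called with the same sign at each. The 12 and 24 h responses of a genotype share their 0 h library. The comparisons, the rule of size, the gene lists, the rule for naming genes and the alternatives were set before the data were examined, except for the length correction and limma's fit on the corrected values, which were chosen after seeing the data.

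Gene lists covered inflammatory mediators (cytokines, chemokines, interferon-stimulated genes, microbicidal genes, feedback inhibitors), macrophage functions (alternative activation, efferocytosis and complement, antigen presentation, lysosome), lipids (eicosanoids, cholesterol synthesis, fatty acid synthesis, LXR targets, fatty acid oxidation, triglyceride and droplet genes, phospholipids), energy and stress (glycolysis, TCA cycle, oxidative phosphorylation, NRF2 targets, unfolded protein response, p53 targets, immediate early and heat shock genes), proliferation, histones, ribosomal proteins, reference genes, neighbours of Setd2, sex-linked genes, enzymes of the same histone residue, and markers of macrophages and 9 other cell types. The median over measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins. Its percentile describes these libraries and is no test of the genotype. Some genes are in more than 1 list, such as Ccl17, Gapdh and Csf3r. The list of LXR targets also holds genes of cholesterol efflux.

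Named genes were chosen by rank among called genes that reached 5 FPKM in a library of the comparison: the 8 highest and 8 lowest for KO against WT at each time, up to 10 each way at all 3 times, the 8 highest and 6 lowest for the WT response, and the 6 highest and 6 lowest for the difference of responses. Of each list, up to 4 members with the largest difference and the called members could be named. Predicted genes, clones and microRNA genes were counted and not named.

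Alternatives were pseudocounts of 0.1 and 5, no minimum FPKM or a minimum of 5, fold rules of 1.5 and 3, median-of-ratios and trimmed-mean (TMM-style) scaling computed on the FPKM values, each pair of the 3 times, and an additive fit of genotype and time with limma. That fit takes the spread of the KO against WT difference over times as its error (robust empirical Bayes with an intensity trend, Benjamini-Hochberg adjustment), so it measures steadiness over times, not replicate error. In the length correction, a lowess curve (span 0.3) of log2 FPKM relative to the mean of all libraries over log transcript length, fitted on genes with a mean of at least 10 FPKM, was centred at its median and taken out of each library, which leaves the scaling as deposited.

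The procedures were tested on simulated data. Calls, the length trend and the scaling were tested on libraries with Poisson counts at the estimated depths, in which 10893 genes were measured. Counting noise alone gave 43, 31 and 45 calls for KO against WT at 0, 12 and 24 h, 46 and 50 for the WT response, 38 and 41 for the KO response, 36 and 45 for 24 h against 12 h in WT and KO, 69 and 79 for the difference of responses, and 1 at all 3 times. Planted folds of 2.5, 4 and 0.25 were called in 100% of 50 genes each at each time, and a fold of 1.5 in at most 2%. Lists were tested not on those libraries but on normal values drawn independently for each gene, with an SD of 0.5 on the log2 scale. Of 100 unshifted lists 7% fell outside percentiles 2.5 to 97.5, and of 50 lists shifted by 0.5 on that scale 92% lay above them. A planted length trend (rho 0.930 at 0 h) was reduced to 0.181, and calls went from 267 to 219 over 17566 genes. The scaling factors were recovered within 0.00113 on the log2 scale. For the limma fit, normal noise of a chosen size was added to the simulated log2 values, with no effect of time. It called 100% of genes planted at 2.5-fold, 90% at 1.5-fold and 32 unchanged genes. The rates for lists and for limma hold for the chosen noise only. These simulations hold no variation between cultures, which no library here can measure.

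Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Reads were not used here, so exons of Setd2, splicing and antisense transcription were not examined. Proteins and lipids were not measured.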

Results

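RNA was sequenced from mouse bone marrow-derived macrophages, which were grown from C57BL/6 bone marrow with the growth factor M-CSF. The cells were wild type (WT) or knockout (KO) for Setd2, a histone methyltransferase whose mark lies over the bodies of transcribed genes. They were collected at 0 h, or after 12 or 24 h with lipopolysaccharide (LPS, a bacterial cell wall component that activates macrophages). The title of the series names lipid metabolism and the end of inflammation as its subject. Each of the 6 groups held 1 library, so no value has a replicate error and no difference between groups has a replicate check. Depth was estimated from the spacing of the deposited values at 21840000 to 22580000 mapped reads per library, if reads were 50 nt long. Between 10023 and 10786 genes reached 1 FPKM in a library. The 10 most abundant genes took 11.9% of the FPKM total in the KO 0 h library and 25.4% in the WT 24 h library, the lowest and highest shares.

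Setd2 (gene ID 235626; GRCm38 chromosome 9, 110532500 to 110618633) was read in every library before any comparison. The WT libraries held 7.83 FPKM at 0 h, 8.68 at 12 h and 7.51 at 24 h. The libraries labelled KO held 9.96, 9.16 and 5.11 FPKM at the same times, from about 958 to 1824 reads each by the depth estimate. On the log2 scale the KO values differed from WT by 0.31, 0.07 and -0.48, all short of the 2-fold rule of size. With the trend over transcript length removed, these became -0.14, 0.00 and -0.21. A gene-level value keeps reads from a transcript that lost only some of its exons, so it does not check the labels. Every direction of KO against WT rests on the labels alone. The 18 measured neighbours of Setd2 on chromosome 9 had median differences of 0.21 (0.08 without that trend), 0.03 and -0.10. Of these, Prss50 was called higher at 0 h (1.15) and at 24 h (1.87), and Nradd at 24 h (1.01). The other 9 enzymes that write or erase methylation at the same histone residue had medians of 0.33, -0.03 and -0.46, with 0 called, and of 0.07, -0.07 and -0.31 without the length trend. Y-linked Eif2s3y lay between 20.4 and 34.1 FPKM in all 6 libraries. The 8 measured sex-linked genes had medians of 0.35, 0.01 and -0.55, with 0 called; without the length trend the first and last were 0.09 and -0.35.

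Part of the difference between libraries followed the length of the transcripts. At 0 h, long transcripts were higher and short ones lower in the library labelled KO, with a Spearman rho across 7634 genes of 0.60 between the log2 difference and length. The median difference was -0.66 for transcripts of up to 512 nt and 0.59 for those over 8192 nt. At 24 h the trend ran the other way, with a rho of -0.44, and medians of 0.17 for the shortest and -0.45 for the longest transcripts. The 12 h pair had a rho of 0.13. Genes are not independent replicates, so each rho describes 1 pair of libraries. Removing the trend from each library brought the 3 values of rho to 0.03, -0.03 and -0.07. Families of short or long transcripts moved with it. The 30 ribosomal protein genes had medians of -0.74, -0.12 and -0.09 as deposited, where trimmed-mean scaling turned the 24 h value to 0.05, and of -0.29, -0.04 and -0.28 without the trend. The 34 nuclear genes of oxidative phosphorylation went from -0.58, -0.12 and 0.14 to -0.10, -0.04 and -0.05.

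**Figure D1:**
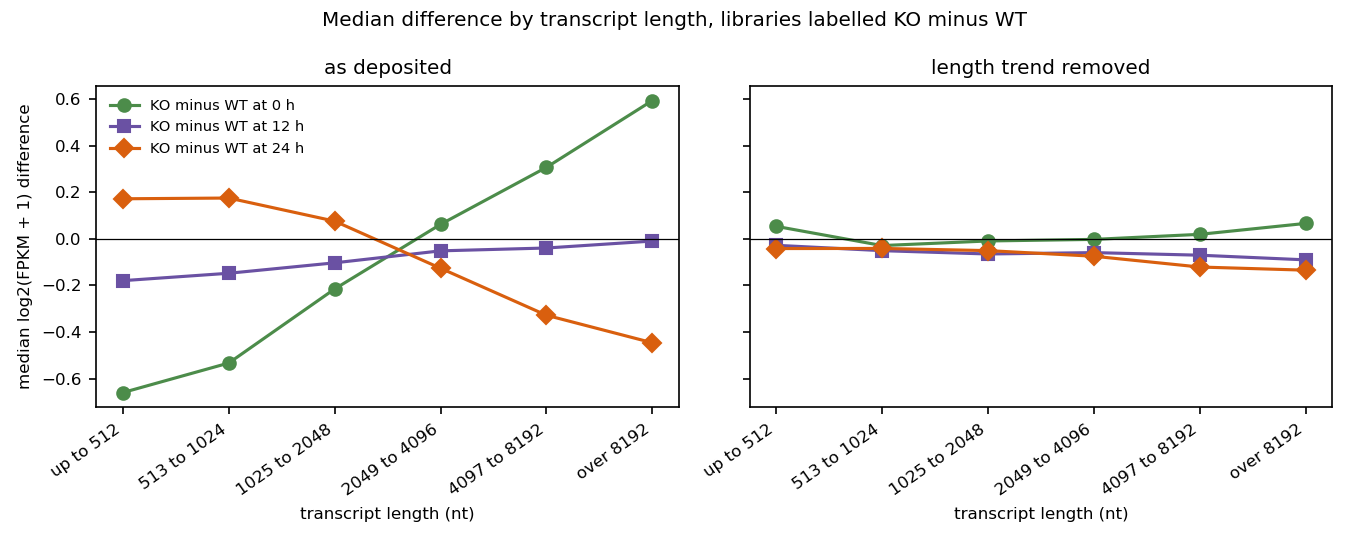
Median log2 difference of KO against WT (y axis) for genes grouped by transcript length in nt (x axis), as deposited (left) and with the length trend removed (right), 1 line per time. As deposited, the 0 h line climbs from -0.66 to 0.59 and the 24 h line descends from 0.17 to -0.45.

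Before LPS was added, the library labelled KO already showed an interferon program relative to WT. An effect of the genotype and a difference of that culture alone cannot be told apart, because the cultures without LPS had no replicates. Interferon-stimulated genes, which encode antiviral proteins, were higher almost across the board. Chemokines that draw monocytes were higher too, and Ccl7 and Ccl2 had the largest positive differences of the ranked genes. Both lysozyme genes were far lower than in WT in the library labelled KO.

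At 0 h, 342 genes were called at least 2-fold higher and 146 lower in the library labelled KO. Simulated libraries with counting noise alone gave 43 calls. With the length trend removed the calls were 325 higher and 80 lower, and 334 genes were called in the same direction both ways. Of 35 interferon-stimulated genes, 32 were called higher and 0 lower, with a median of 1.78 at percentile 100 of random lists matched on expression. Ifit3, an antiviral gene of this list, was higher by 3.31, from 3.34 FPKM in WT to 42.1. The antiviral synthetase relatives Oasl2 (3.22) and Oasl1 (2.86) followed, with Usp18 (2.86), which removes ISG15 from proteins. Irf7, the transcription factor that amplifies type I interferon, went from 18.7 to 153 FPKM, a difference of 2.97. Siglec1, a sialic acid receptor induced by interferon, was higher by 3.09. The 20 chemokine genes had a median of 0.57, with 8 called higher and 0 lower. Ccl7 stood at 1.06 FPKM in WT and 82.5 in KO (5.34), and Ccl2 at 11.7 and 282 (4.48). Cxcl10, a ligand of the chemokine receptor Cxcr3, was higher by 2.41, Ccl12 by 2.04 and the neutrophil attractant Cxcl2 by 1.19. The remaining calls in the list were Ccl6 (1.49), Ccl4 (1.07) and Ccl3 (1.07).

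Inflammatory cytokines had a median of 0.28 over 17 genes at 0 h, and of 0.60 without the length trend, where chemokines were at 0.69. Csf1, which encodes M-CSF itself, was the 1 called member (1.51). Among 26 feedback inhibitors of inflammatory signalling (median 0.18), Il1rn, the natural antagonist of interleukin 1, was higher by 1.96. Dusp4 (1.67), Socs1 (1.53) and Tnfaip3 (1.23) were the other called members. Stress gene medians were 0.31 over 17 NRF2 targets and 0.27 over 20 genes of the unfolded protein and integrated stress responses. Hmox1, which degrades heme, was higher by 1.41, Slc7a11 by 1.08, Ddit3 by 1.24, Trib3 by 1.18 and Chac1 by 1.03. Lyz2 was the lowest of the ranked genes, with 5502 FPKM in WT and 17.7 in KO (-8.20), followed by its neighbour Lyz1 (-5.57). Sap25 (-2.55), Rsc1a1 (-1.95), Frat2 (-1.86, and -0.91 with a pseudocount of 5) and Ugt1a6b (-1.71) were also among the lowest. Fabp4, a carrier of fatty acids, was lower (-2.12), and Hpgd, which breaks down prostaglandins, (-1.64). The apolipoprotein genes Apoc2 (-1.18) and Apoe (-1.04) were called lower and Ch25h, which makes an oxysterol, was called higher (1.55). Those 3 belong to a list of 20 genes that joins targets of the sterol-sensing receptor LXR with cholesterol efflux genes. Its median was -0.06, and -0.17 without the length trend. Apoc2 (-0.62) and Apoe (-0.74) were then no longer called. Cholesterol synthesis (25 genes) had a median of -0.26, and fatty acid synthesis (16 genes) 0.04, with 0 called in both.

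After 12 h with LPS the libraries were closest to each other. The antiviral program was up in both, and little of the earlier gap was left. Some chemokines and cytokines were higher in the library labelled KO, among them the genes for interleukins 1α, 6 and 12. Arginase, which competes with nitric oxide synthase for arginine, was lower.

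At 12 h, 152 genes were called higher and 84 lower, against 31 calls from simulated counting noise. Without the length trend there were 160 and 82, with 223 genes called alike both ways. The median of interferon-stimulated genes was 0.37, still at percentile 100 of random lists, but only Gbp3 (1.08) was called of the 35. Chemokines had a median of 0.74 and 7 calls, all higher: Ccl12 (2.04), Ccl7 (1.96), Cxcl11 (1.91), Ccl17 (1.80), Ccl2 (1.79), Ccl8 (1.58) and Cxcl10 (1.08). The cytokine median was 0.57. Il12b, a subunit of interleukins 12 and 23 that steers T cells, was higher by 1.85. Il1a (1.54), Il6 (1.41) and Csf1 (1.26) were called as well. Lipg, an endothelial-type lipase, had the largest positive difference of the ranked genes at 3.02. Next came the vasoconstrictor gene Edn1 (2.46) and Hamp, which encodes the iron hormone hepcidin (2.28). Slamf1, a receptor on activated leukocytes, was higher by 1.82. On the lower side, Lyz2 (-6.72) and Lyz1 (-4.82) were first. Rps27rt (-3.66) is listed at 0 in all libraries but WT 12 h. Arg1 was at 40.2 FPKM in WT and 7.97 in KO (-2.20), while Nos2, the inducible nitric oxide synthase, was higher by 1.22. Mcemp1 (-1.62), Tmem119 (-1.54), Glrx (-1.52) and the lectin receptor gene Clec4a2 (-1.52) completed the lowest 8 of the ranked genes. Fatty acid synthesis had a median of -0.27 with Scd2, a stearoyl-CoA desaturase, called lower (-1.11), and cholesterol synthesis stood at -0.28. Glycolysis and hypoxia genes (27) were at -0.31 and proliferation genes (32) at -0.49, with Mcm7 (-1.20) called.

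By 24 h most chemokines were higher and some lipid-making genes lower in the macrophages labelled KO. The monocyte attractants Ccl2 and Ccl7 were still high there, when those of WT had come down. The lower genes included some enzymes of cholesterol and fatty acid synthesis and the cholesterol exporter Abca1. Lipoprotein lipase and a few genes of lipid droplets were higher. Interleukin 10 and the interleukin 1 antagonist, both brakes on inflammation, were higher as well.

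At 24 h, 256 genes were called higher and 223 lower in the library labelled KO, with 45 calls from simulated counting noise. The balance depends on the settings. A pseudocount of 0.1 gave 430 higher and 677 lower, and a 1.5-fold rule 700 and 1251. Trimmed-mean factors gave 333 and 162, and moved the median of genes with a mean of at least 5 FPKM from -0.09 to 0.04. Removing the length trend left 208 higher and 179 lower, and 363 genes were called alike both ways. The chemokine median reached 1.87, with 15 of 20 called higher and 0 lower. Ccl2 was at 108 FPKM in WT and 1638 in KO (3.91), Ccl7 at 23.1 and 832 (5.11), and Ccl12 at 24.7 and 290.0 (3.50). Members that recruit neutrophils were among them, with Cxcl3 higher by 1.97, Cxcl1 by 1.74, Cxcl5 by 1.56 and Cxcl2 by 1.23. Others were Ccl4 (2.08), Ccl6 (2.05), Ccl8 (2.03), Ccl17 (1.96), Ccl3 (1.93), Cxcl10 (1.92), Cxcl11 (1.83) and Ccl9 (1.64). Of the cytokines (median 0.64), Il1a was higher by 2.92, Csf3, which drives neutrophil production, by 2.70, Il12b by 1.59, Il6 by 1.56, Tnf by 1.34 and Csf1 by 1.02. In the feedback list (median 0.28), Il1rn (2.26), Il10 (1.94), Socs1 (1.38) and Dusp2 (1.05) were called. Interferon-stimulated genes had a median of 0.45, and Oasl1 (1.66), Isg20 (1.19), Ifit3 (1.14) and Isg15 (1.09) were called. Without the length trend Isg20 (0.96), Isg15 (0.86) and Dusp2 (0.93) lost their calls.

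Cholesterol synthesis had a median of -0.85 at 24 h, at percentile 0 of random lists, and 7 of its 25 genes were called lower. Among them, the sterol carrier Stard4 was lower (-1.53), with Idi1 (-1.26), Cyp51 (-1.17), Dhcr7 (-1.17), Nsdhl (-1.04) and Fdps (-1.01). For fatty acid synthesis the median was -0.76, also at percentile 0, with 5 of 16 called lower. Scd2 (GRCm38 chromosome 19, 44293676 to 44306864) was at 23.5 FPKM in WT and 3.55 in KO (-2.43). Fatty acid synthase, Fasn, was lower (-1.37), the desaturase Fads2 (-1.24), Acsl3 (-1.08) and Mid1ip1 (-1.03). The list of LXR targets and cholesterol efflux had a median of -0.42. There, Abca1, which pumps cholesterol to apolipoprotein A1, was lower (-1.66), Apoc2 (-1.23), Mylip, a ubiquitin ligase, (-1.19), and Pltp (-1.16), while Ch25h was higher by 2.31. With the length trend removed these 3 medians were -0.77, -0.69 and -0.37. In the list of triglyceride, droplet and uptake genes the median was -0.03 over 27 members that split. Lpl (1.97), Fabp3 (1.71), Hilpda (1.41) and the droplet coat gene Plin2 (1.36) were higher, and Fabp4 (-1.58) was lower.

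Other genes with large differences at 24 h were Hist2h3c2 (3.08), Upp1, a uridine phosphorylase (2.61), and Id1, an inhibitor of basic helix-loop-helix factors (2.54). Histone transcripts as a list had a median of 1.39 over 6 measured genes, with Hist2h2aa1 (2.14), Hist1h2be (1.46), Hist1h4h (1.42) and Hist1h2bc (1.36) called. Lyz2 (-7.34) and Lyz1 (-5.54) were again lowest. Lyz1 and Lyz2, the histone genes, Rps27rt and the pseudogene Atp6v0c-ps2 resemble other genes closely, so how reads were split among the copies is uncertain. F13a1, a transglutaminase of coagulation, was lower (-2.19), the chemokine receptor gene Cxcr4 (-2.17), Cd300lh (-2.13), Nxpe5 (-2.11) and Mob1a (-2.05). Of 27 glycolysis and hypoxia genes (median -0.15), 3 were called lower: Hif1a (-1.49), Egln3 (-1.16) and Vegfa (-1.14). In the stress list (median -0.40), Phgdh (-1.24) and Asns (-1.17), which make serine and asparagine, were called lower. Cybb, the catalytic subunit of the phagocyte oxidase, was lower (-1.09), and -0.86 without the length trend, short of a call.

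**Figure D2:**
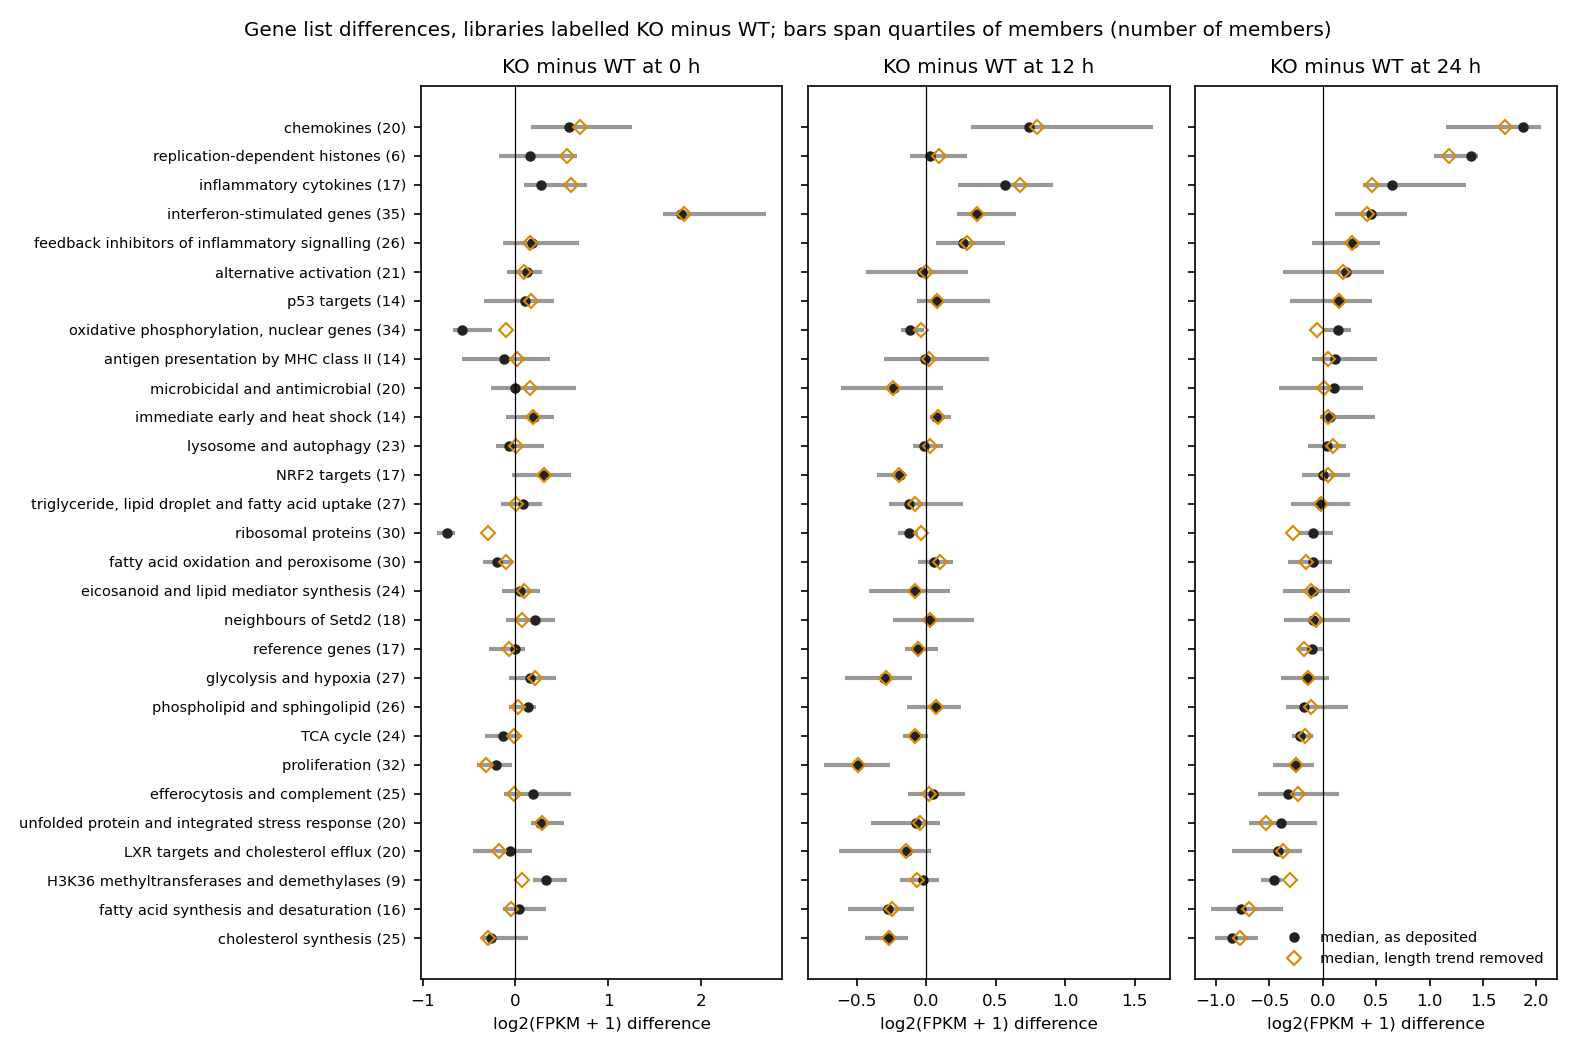
Median log2 difference of KO against WT (x axis) of each gene list (y axis) at 0, 12 and 24 h, 1 panel per time. Black dots are the values as deposited, orange diamonds have the length trend removed, and bars span the quartiles of the members. Interferon-stimulated genes lead at 0 h (1.78) and chemokines at 24 h (1.87), with cholesterol synthesis lowest at 24 h (-0.85).

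The remaining lists held fewer calls. Efferocytosis and complement genes, which serve the clearance of dead cells, had medians of 0.19, 0.05 and -0.32 at 0, 12 and 24 h; the first became -0.01 without the length trend. Within that list Cd300lf was called higher at all 3 times (1.55 at 0 h and 2.14 at 24 h), Axl at 0 h (1.54) and 12 h (1.08), and Havcr2 at 24 h (1.35). C1qa was lower at 0 h (-1.50) and 12 h (-1.17), and Mertk, a receptor for dying cells, at 24 h (-1.01). Alternative activation genes stood at 0.13, -0.03 and 0.21. They included Tgm2 (1.59) and Myc (1.56) at 0 h, and Myc (1.27) and Trem2 (1.08) at 24 h, when Arg1 was called lower. Microbicidal genes had medians of -0.01, -0.23 and 0.10, with Ass1 (1.35) and Acod1 (1.13) called higher at 0 h. Eicosanoid genes were at 0.05, -0.08 and -0.09, with Pla2g16 called higher at 24 h (1.21). Phospholipid and sphingolipid genes were at 0.14, 0.07 and -0.18, with Cers6 called higher at 0 h. Of the uptake genes (0.08 at 0 h and -0.12 at 12 h), Msr1 was higher at 0 h (1.04), and at 12 h Lpl was higher (1.16) and Mgll lower (-1.03). Fatty acid oxidation had medians of -0.20, 0.06 and -0.09, with 0 of 30 genes called.

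For glycolysis and hypoxia the medians were 0.16 at 0 h, with Pfkfb3 (1.36) and Slc2a1 (1.03) called, and -0.15 at 24 h. TCA cycle genes were at -0.13, -0.08 and -0.21, with Idh1 called lower at 24 h (-1.17). NRF2 targets were at -0.19 at 12 h and 0.00 at 24 h, and the stress responses at -0.07 at 12 h. Lysosome genes (-0.07, -0.01 and 0.04) had 0 calls among 23. Antigen presentation genes were at -0.12, -0.01 and 0.11, with Cd40 called at 12 h (1.27) and Cd86 at 24 h (1.19). Proliferation was at -0.20 at 0 h, with Tk1 (-1.03) and Birc5 (-1.03) called, and at -0.26 at 24 h. The p53 targets were at 0.10, 0.08 and 0.15, with Sesn1 called lower at 24 h (-1.06). Immediate early and heat shock genes were at 0.20, 0.07 and 0.07, with Jun called at 0 h (1.03) and Hspb1 at 24 h (1.06). The feedback list was at 0.27 at 12 h, with 0 called. Histone genes were at 0.15 and 0.03 before 24 h. Reference genes had medians of 0.00, -0.06 and -0.10, with Polr2a called higher at 0 h (1.01). Rpl37a (-1.05 at 0 h) was the 1 ribosomal call. Without the length trend the 0 h calls of Cers6, Tk1, Birc5, Slc2a1, Slc7a11, Jun, Polr2a and Rpl37a were lost, as were the 24 h calls of Mertk, Trem2, Sesn1, Hspb1 and Nradd. Several 0 h medians also moved, to -0.10 for fatty acid oxidation, 0.02 for phospholipid genes, -0.02 for the TCA cycle, 0.01 for antigen presentation, 0.16 for microbicidal genes, -0.32 for proliferation and 0.56 for histones. At 24 h fatty acid oxidation went to -0.16 and the stress responses to -0.53.

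Markers of cell types were read in the same way. Macrophage markers (16 genes, Lyz2 included) were at -0.04, -0.36 and -0.26, with Itgam called lower at 24 h (-1.24). Neutrophil markers (13 genes) were at -0.18, -0.22 and -0.14, with S100a8 lower at 12 h (-1.16). Dendritic cell markers (8 genes) were at 0.21, 0.12 and 0.07. The 1 measured B cell marker was at -0.57, -0.36 and -0.16, and the 3 of T and NK cells at -0.20, 0.51 and -0.13. Medians for 2 mast cell genes were -0.08, 0.12 and 0.72, with Hdc at 1.65 at 24 h, and for 4 erythroid and megakaryocyte genes -0.06, -0.08 and -0.13, with Pf4 at 1.48. Fibroblast markers (8 genes) were at 0.25, 0.18 and -0.13, with Dcn at 1.13 at 24 h. Endothelial and epithelial markers (4 genes) were at 0.20, 0.31 and -0.02, with Kdr at 1.31 at 0 h. Osteoclast markers (9 genes) were at 0.11, -0.20 and -0.10, with Ocstamp at 1.58 at 12 h. B cell, T and NK cell, mast cell and erythroid lists are too short to describe a cell type. Once the length trend was removed, the 0 h medians were -0.31 for B cell, -0.41 for T and NK cell, 0.28 for erythroid, -0.05 for endothelial and -0.04 for osteoclast markers, and macrophage markers were at -0.24 at 12 h.

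A small set of genes differed at every time, whether or not LPS was present. The monocyte attractants Ccl2, Ccl7 and Ccl12 headed it. Plau, the urokinase that activates plasmin, and the macrophage elastase Mmp12 were in it. Both lysozyme genes were low throughout.

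At all 3 times together, 16 genes were called higher and 3 lower. The 3 differences share no library, though the labels do not say whether cultures or animals were shared. If 1 time is taken with its sign turned, 2 or 3 genes pass instead of 19, and simulated counting noise gave 1. Requiring only 2 of the times gave 47 genes for 0 and 12 h, 63 for 0 and 24 h, and 77 for 12 and 24 h. With the length trend removed 21 were higher and 5 lower, and 15 and 3 of the first set were among them. As means over the 3 times with their SD (n = 3 times), Ccl7 was higher by 4.14 ± 1.89, Ccl2 by 3.39 ± 1.42, Ccl12 by 2.53 ± 0.84 and Cxcl10 by 1.80 ± 0.67. Plau followed at 1.52 ± 0.32, the metalloprotease gene Adam33 at 1.49 ± 0.22, Ly6a (Sca-1) at 1.48 ± 0.41, Ifit1bl1 at 1.49 ± 0.38, Glipr2 at 1.32 ± 0.17 and Treml2 at 1.29 ± 0.28. The values were -7.42 ± 0.74 for Lyz2 and -5.31 ± 0.42 for Lyz1. Ccl2 (82035577 to 82037452), Ccl7 (82045712 to 82047525) and Ccl12 (82101845 to 82103399) lie side by side on chromosome 11. Lyz2 (117277541 to 117282272) and Lyz1 (117287795 to 117292868) are neighbours on chromosome 10. Cd300lf, Csf1, Ifi205 and Mmp12 were also higher and Xlr3b lower; Ifi205, Mmp12 and Xlr3b are named after their values were seen. Across genes, the differences at 0 and 12 h had a Pearson r of 0.42 (7676 genes), those at 12 and 24 h 0.42, and those at 0 and 24 h 0.02. Spearman's rho for the same pairs was 0.34, 0.28 and -0.19. Without the length trend the pair of 0 and 24 h had an r of 0.26 and a rho of 0.11.

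An additive fit of genotype and time with limma took the spread between times in place of replicate error. It called 2 genes, Lyz1 and Lyz2, each with limma's adjusted p of 0.000307, lower in 3 of 3 libraries labelled KO.

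**Figure D3:**
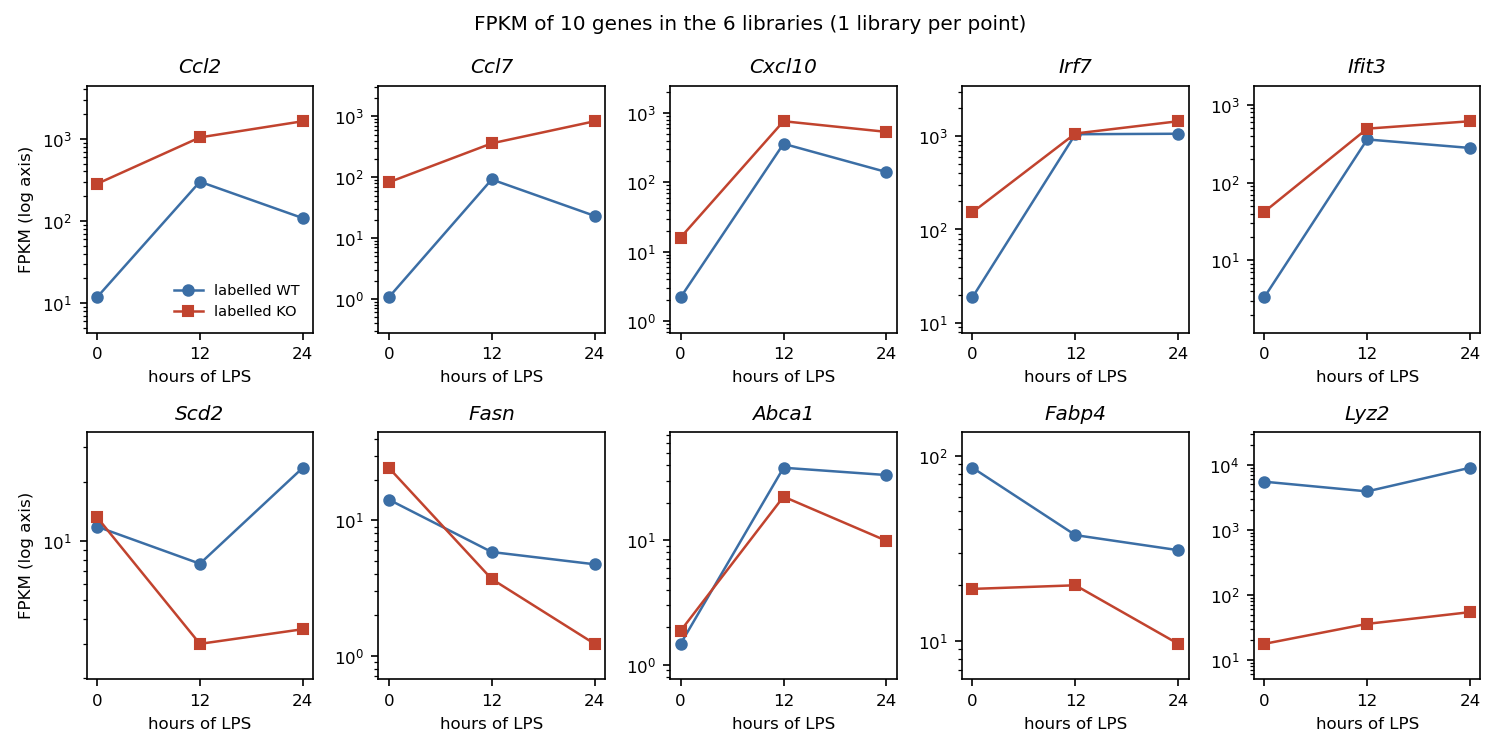
FPKM on a log axis (y) over hours with LPS (x) for 10 genes, WT in blue and KO in red, with 1 library per point and therefore no error bars. Ccl2 and Ccl7 lie higher in KO at each time, Irf7 and Ifit3 mainly at 0 h, and Scd2 and Abca1 lower in KO at 24 h.

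In WT macrophages LPS set off the program known for this stimulus. Interferon-stimulated genes, most chemokines and cytokines, and many microbicidal genes, were higher by several fold. Proliferation genes were shut down. Many glycolysis genes were higher, while some genes for making cholesterol were lower.

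At 12 h in WT, 1113 genes were called higher and 2011 lower, and at 24 h 883 and 1601; both times share the 0 h library. The split depends on scaling, because the median of genes with a mean of at least 5 FPKM lay at -0.27 and -0.24. Median-of-ratios factors brought it to -0.03 at both times, with 1406 higher and 1390 lower at 12 h and 1068 and 1153 at 24 h. Trimmed-mean factors gave -0.01 and 0.04, with 1437 and 1332, and 1156 and 1048. All 35 interferon-stimulated genes were called higher at both times, with medians of 4.60 and 3.79. Rsad2, which makes an antiviral nucleotide, was higher by 6.81 at 12 h. Chemokine medians were 3.01 and 1.99 (Cxcl10 6.82 at 12 h, Cxcl3 6.91 at 24 h), microbicidal 2.73 at 12 h, feedback inhibitors 2.31 and 1.68, and cytokines 1.88 and 1.21. Il1b was higher by 7.90 at 12 h and 7.91 at 24 h. The acute phase gene Saa3 went from 75.3 FPKM to 17094 and then to 49931 (7.81 and 9.35). Acod1, which makes itaconate, was higher by 7.52 and 7.16, Nos2 by 7.07 and 6.95, and complement factor B, Cfb, by 7.06 and 7.70. Ptges, the prostaglandin E synthase, was higher by 7.14 at 12 h, and the formyl peptide receptor genes Fpr1 (7.53) and Fpr2 (7.36) at 24 h. Proliferation medians were -2.65 and -3.94, with 31 of 32 called lower at both times. Ccnb2 (-3.85) and Birc5 (-3.80) were among the lowest genes at 12 h, with Hpgd (-4.49), Fam64a (-4.17), Pcp4l1 (-4.14) and Sap25 (-3.96). At 24 h the lowest were Birc5 (-5.83), Stmn1 (-5.70), Id3 (-5.68), Rrm2 (-5.61), Ccna2 (-5.33) and Pcp4l1 (-5.26). Cholesterol synthesis had medians of -0.81 and -0.84, fatty acid oxidation -0.71 and -0.58, and fatty acid synthesis -0.48 and -0.43, at percentiles 17.3 and 13.0 of random lists. The last list was at -0.77 at 12 h without the length trend. Glycolysis was at 0.64 and 1.35, and NRF2 targets at 0.64 and 1.04.

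Macrophages labelled KO shared many of their LPS-responding genes with WT. Their interferon response was smaller in size, from a higher starting level. Some lipid-making genes were lower than in WT by 24 h.

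In the KO libraries 996 genes were called higher and 2020 lower at 12 h, and 872 and 2489 at 24 h. Median-of-ratios factors gave 1256 and 1334, and 1104 and 1901. Under trimmed-mean factors the counts were 1344 and 1180, and 1516 and 1354, with the all-gene median moving from -0.34 to 0.00 at 12 h and from -0.32 to 0.13 at 24 h. Of the genes called higher in WT at 12 h, 796 (71.5%) were called higher in KO, where independent lists would share 96.0. For those called lower, 1320 (65.6%) were shared, against 352. At 24 h 602 higher (68.2%) and 1121 lower calls (70.0%) were shared, against 66.7 and 345. As shares of the KO calls these were 79.9% and 65.3% at 12 h, and 69.0% and 45.0% at 24 h. The 24 h values were 55.3% and 52.1% under trimmed-mean factors, and 75.5% and 56.0% without the length trend. The responses of WT and KO had a Pearson r across genes of 0.92 at 12 h and 0.83 at 24 h. Spearman's rho was 0.86 and 0.63, and 0.89 and 0.78 without the length trend. Called in opposite directions were 18 genes at 12 h and 26 at 24 h, differences that were not tested. KO medians at 12 and 24 h were 2.92 and 2.66 for interferon-stimulated genes, 3.67 and 2.83 for chemokines, and 2.29 and 1.70 for cytokines. As deposited, cholesterol synthesis stood at -0.80 and -1.63, with 19 of 25 genes called lower at 24 h against 10 in WT. Part of that contrast may be scaling, since trimmed-mean factors moved the 24 h all-gene median further in KO than in WT (-0.24 to 0.04). Fatty acid synthesis stood at -1.14 and -1.43.

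Between 12 and 24 h the medians of cytokines, interferon-stimulated genes and feedback inhibitors came down by similar amounts in WT and KO. The chemokine median came down in WT, and in the libraries labelled KO its direction depended on the length trend. A few genes for fatty acid synthesis were higher at 24 h in WT. The glycolysis medians were above 0 in both, with few genes called in WT.

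From 12 to 24 h, 210 genes were called higher and 438 lower in WT, and 552 and 886 in KO. The KO counts became 281 and 619 without the length trend, and 760 and 738 under trimmed-mean factors, which moved the all-gene median from -0.03 to 0.08. Cytokine medians were -0.77 in WT, with 8 of 17 called lower, and -0.87 in KO, with 7. The chemokine median was -1.07 in WT, with 10 called lower and 0 higher, against 0.20 in KO, with 4 called each way; without the length trend the KO value was -0.29, with 0 higher and 7 lower. In WT, Csf3 (-3.13), Il1a (-2.60), Ccl22 (-2.50), Ccl9 (-2.47) and Ccl7 (-1.94) were much lower at 24 h, and in KO Cxcl3 was higher (1.47). Interferon-stimulated genes were at -0.53 and -0.66 and feedback inhibitors at -0.53 and -0.59. Fatty acid synthesis was at 0.29 in WT, with Scd2, Me1 (1.07), Mid1ip1 (1.04) and Fads1 (1.02) higher, and at -0.04 in KO, with Fasn lower (-1.08); without the length trend Mid1ip1 (0.99) and Fasn (-0.53) were not called. Cholesterol synthesis was at -0.24 in WT and -0.85 in KO (-0.14 and -0.67 without the trend), where Hmgcs1 (-1.47), Hsd17b7 (-1.40) and Idi1 (-1.31) were among the calls. Glycolysis was at 0.64 in WT, with 1 of 27 called higher, and at 0.62 in KO, with 10 called. Histone genes were at 0.68 in WT, and in KO 6 of 6 were called higher.

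The difference between the LPS responses shows which genes reacted more or less in the macrophages labelled KO. Most interferon-stimulated genes reacted less, from their higher level at 0 h; both times share the 0 h libraries, so they are not separate observations. Some chemokines and a few cytokines reacted more at 24 h. A few genes of cholesterol and fatty acid synthesis, and of the hypoxia response, reacted less or were driven lower at 24 h.

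At 12 h the response was higher in KO for 190 genes and lower for 363, against 69 calls from simulated counting noise. At 24 h it was higher for 467 and lower for 997, against 79. The 24 h counts followed transcript length (rho -0.67) and became 246 and 515 without the trend, and 764 and 703 under trimmed-mean factors, with the all-gene median going from -0.09 to 0.07. Interferon-stimulated genes had medians of -1.52 and -1.50, each with 26 lower. At 12 h Irf7 was at -2.94, Rtp4 at -2.91, Oasl2 at -2.86 and Ifit3 at -2.85, with Ccl7 at -3.38 and Rps27rt at -3.66. At 24 h Siglec1 was at -3.29 and Oasl2 at -3.20. Higher at 12 h were Sap25 (3.62), Edn1 (2.37), Lipg (2.31, and 0.35 with a pseudocount of 0.1), Hamp (2.12), the MHC gene H2-Q8 (1.97) and Pdzk1ip1 (1.82). The chemokine median was -0.12 at 12 h (-0.26 without the trend) and 0.88 at 24 h. There 9 were called higher and 0 lower, or 6 and 1 without the trend, with Ccl8 (1.78), Ccl17 (1.72), Cxcl11 (1.62) and Cxcl1 (1.57) highest. Cytokine medians were 0.24 and 0.32, with Csf3 (2.64), Il1a (2.06) and Il6 (1.29) called at 24 h, and Il10 was at 2.18. Without the length trend the cytokine medians were 0.09 and 0.03, with 3 called higher and 1 lower at 24 h. Cholesterol synthesis was at -0.03 and -0.70 (5 of 25 lower at 24 h) and fatty acid synthesis at -0.36 and -0.74 (4 of 16). The list of LXR targets and cholesterol efflux was at -0.04 and -0.33. At 24 h Scd2 stood at -2.58, Fasn at -2.11, Abca1 at -1.88, Stard4 at -1.71 and Hsd17b7 at -1.49. Lpl (1.72), Hilpda (1.63) and Fabp3 (1.41) went the other way, and without the length trend Hilpda (0.97) and Fabp3 (0.70) were not called. Glycolysis and hypoxia medians were -0.52 and -0.20 (7 of 27 lower at 24 h). With the length trend removed, 3 cholesterol, 3 fatty acid synthesis and 5 glycolysis and hypoxia genes were lower at 24 h, with medians of -0.51, -0.57 and -0.36. As deposited, Pfkfb3 of the glycolysis and hypoxia list, which speeds glycolysis, was at -1.28 and -2.34 at 12 and 24 h. Hif1a was at -1.07 and -1.98, and Vegfa at -1.50 at 24 h. The 12 h value of Hif1a was -0.84 without the trend. The largest values at 24 h also included Rsc1a1 (4.14), Id3 (3.29), Atp6v0c-ps2 (2.94), Upp1 (2.49) and Malat1 (2.42), and on the lower side Uhmk1 (-3.11), Mgat5 (-3.08), Mob1a (-3.08) and Cbl (-3.06). Some of these had opposite directions in WT and KO.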

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

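The tests of a length trend, of RNA from LPS-treated cells, of scaling and of macrophage share were chosen after the result was seen. So were those of reads shared between paralogs and of single cultures. The test of the region around Lyz2 was set before its own value was seen, but it concerns a result found in these data. A spread given with a median is the SD of that median over resamplings of its genes. It treats genes as independent and holds no variation between libraries or cultures. For a difference of medians, the SDs of both were combined.

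Named genes went in opposite directions at different times or in the different genotypes, and none of these differences was tested, since each rests on single libraries. The log2 values of KO against WT were -1.95 at 0 h and 2.19 at 24 h for Rsc1a1, 4.14 apart, and its LPS response at 24 h was -1.64 in WT and of the other sign in KO, again 4.14 apart. For Atp6v0c-ps2 they were -1.37 and 1.58 (2.94 apart), and for the nuclear RNA Malat1 -1.26 and 1.16 (2.42 apart). The opposite order held for Mgat5 (1.78 and -1.29, 3.08 apart), Uhmk1 (1.87 and -1.24, 3.11 apart) and Mob1a (1.02 and -2.05, 3.08 apart). Sap25 was at -2.55 at 0 h and 1.07 at 12 h, 3.62 apart. Cbl responded to 24 h of LPS by 1.44 in WT and -1.62 in KO, a difference of -3.06. With the length trend removed, Mgat5 (1.37 and -1.13), Uhmk1 (1.47 and -1.06) and Malat1 (-1.69 and 1.44) were still called both ways, and Mob1a (0.79 and -1.86) was not.

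Interferon-stimulated genes stood 1.78 above WT in the library labelled KO at 0 h. Removing the length trend left 1.81, which argues against that trend as the cause. RNA from LPS-treated cells would need a share of 10.9% to give the list its values, with WT 12 h as source. The 20 most abundant other LPS-induced genes allowed a median of 1.13% with that source. Single genes of the 20 ran from -6.10% (Prdx5) to 24.5% (Ifitm3), and Saa3 was no higher in KO (61.4 FPKM) than in WT (75.3). A first version over all 204 other induced genes gave 4.20%, and the abundant genes were chosen after it. With WT 24 h as source the 3 shares were 18.2%, 2.28% and 6.41%. The first version did not meet the limit written for this test with either source. The medians of the 204 and of the 20 genes still lay below the share of the list with either source, beyond their spreads. With WT 12 h as source the spread was 2.52 for the list, 0.60 for the 204 genes and 1.08 for the 20. These values argue against such RNA as the whole source of the list's values, and a smaller share is not excluded. A difference of that 1 culture, such as a passing exposure to interferon, and an effect of the genotype cannot be told apart, because the list at 24 h (0.45) comes after LPS had induced it in both, so a tonic interferon signal in Setd2-deficient macrophages stays a hypothesis that replicate cultures without LPS could test.

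Lyz2 was at 0.322%, 0.921% and 0.605% of WT in the libraries labelled KO at 0, 12 and 24 h, and Lyz1 at 1.93%, 3.23% and 2.03%. Fewer macrophages would lower the other macrophage markers alike, but the median of 15 was -0.20 with a spread of 0.13. A change of the whole chromosome region is argued against by 9 other measured genes within 500 kb, with a median of -0.029 and a spread of 0.14. Lyz1 ran at 28.8% to 62.0% of Lyz2 in KO and at 8.21% to 10.3% in WT; whether reads of Lyz2 counted as Lyz1 account for the low Lyz1 values cannot be told apart from a true loss without the reads. A candidate explanation is an engineered Lyz2 locus, such as a Cre recombinase placed in Lyz2 to delete Setd2 in myeloid cells; the labels name no such allele and it was not tested.

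Cholesterol and fatty acid synthesis genes together (41) had a median of -0.82 at 24 h, with 12 called lower and 0 higher. Without the length trend it was -0.75, with a spread of 0.06, so the trend is argued against. Set against the median of genes with a mean of at least 5 FPKM it was -0.73, which argues against another scaling of that library. At 12 h the median was -0.28, and at 0 h it was -0.12 with a spread of 0.10 and lists that disagreed (cholesterol -0.26, fatty acid 0.04). The KO 24 h library also stood out in histone transcripts and Malat1, as given below. A difference of the 24 h culture or library and an effect of the genotype therefore cannot be told apart. Lower activity of the sterol-sensing factors that drive both pathways may be a biological source, a hypothesis from the data it was seen in that replicate cultures with measured sterols could test.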

How the results depend on the processing

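The length correction and limma's fit on corrected values were chosen after the data were seen; all other alternatives were set in advance. Of the counts of called genes under alternatives, 61 lay within 1.5 times the reported count and 52 did not. Of list medians, 586 moved little, 128 moved and 3 were marked as reversed, a label that did not cover every change of sign. For named genes, 496 values kept direction and call and 2 kept direction only, and the 9 values of Setd2 stayed uncalled.

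With a pseudocount of 0.1 the KO against WT calls were 867, 517 and 1107 at 0, 12 and 24 h and 62 at all 3 times, 24 h against 12 h gave 1262 in WT and 2365 in KO, and the difference of responses gave 1068 at 12 h and 2338 at 24 h. With a pseudocount of 5 the calls were 145, 54 and 135, 8 at all 3 times, 1750 and 1371 for the WT response, 1524 and 1662 for the KO response, 243 and 546 for 24 h against 12 h, and 156 and 487 for the difference of responses. A larger pseudocount shrinks differences of weak genes, by construction. A 1.5-fold rule gave 1992, 926 and 1951, 119 at all 3 times, 5766 and 4717 for WT, 5710 and 6139 for KO, 2088 and 3927 for 24 h against 12 h, and 2226 and 4282 for the difference of responses. A 3-fold rule gave 127, 49 and 97, 5 at all 3 times, 1372 and 1169, 1286 and 1469, 153 and 294, and 147 and 329 in the same order. A minimum of 5 FPKM left 128 calls at 12 h for KO against WT. Those counts move by construction, since the rule itself changed. Removing the length trend took 24 h against 12 h in KO to 900 and the difference of responses at 24 h to 761. Asking for 2 of the 3 times gave 47 (0 and 12 h), 63 (0 and 24 h) and 77 genes (12 and 24 h). The limma fit called 2 genes, as deposited and with the length trend removed.

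The chemokine median at 0 h was 1.11 with a pseudocount of 0.1, 0.27 with 5, 0.41 among members reaching 5 FPKM and 0.69 without the length trend. At 12 h it was 0.81 with median-of-ratios factors, and at 24 h 1.51 with a pseudocount of 5, 2.02 with trimmed-mean factors and 1.71 without the trend. For interferon-stimulated genes it was 2.38 and 1.40 at 0 h with pseudocounts of 0.1 and 5, 0.44 at 12 h with median-of-ratios factors and 0.60 at 24 h with trimmed-mean factors. For cholesterol synthesis it was -0.21 at 12 h with a pseudocount of 5 and -0.21 with median-of-ratios factors, and at 24 h -0.94 and -0.64 with pseudocounts of 0.1 and 5 and -0.73 with trimmed-mean factors. For fatty acid synthesis it was -0.17 at 12 h with a pseudocount of 5, and at 24 h -0.91, -0.45 and -0.64 under the same 3 settings. Medians marked as reversed were efferocytosis at 0 h (-0.012 without the length trend), ribosomal proteins at 24 h (0.052 with trimmed-mean factors) and T and NK cell markers at 12 h (-0.15 at a minimum of 5 FPKM). Other medians changed sign too, among them oxidative phosphorylation at 24 h and antigen presentation at 0 h without the length trend. Frat2 at 0 h was at -0.91 with a pseudocount of 5, and the difference of responses of Lipg at 12 h was 0.35 with 0.1. Apart from settings where construction shows it, the cause was not tested.

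No paired analysis was possible by replicate number because each group holds 1 library; the limma fit sets KO against WT within each time. Counts scaled by depth (CPM) could not be used as an alternative, because the deposited table holds FPKM alone. At the estimated depth, simulated counting noise gave 31 to 45 calls for KO against WT; variation between cultures has no estimate here.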

Other observations

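The comparison of KO 24 h with the other libraries, and the readings of Ifnb1 and Csf1, were noted after the values were seen. The tests of LPS-induced genes coming down, of the Ccl2 region and of other splits of the libraries were set before their values were seen. The test of the Ccl2 region concerns a result found in these data.

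The series names the end of inflammation, so one hypothesis was that LPS-induced genes come down less by 24 h in the macrophages labelled KO. The 197 genes higher at 12 h and lower at 24 h in WT had a median of -1.34 from 12 to 24 h, and -1.42 in KO. For 242 genes chosen in KO the median was -1.39 there and -1.01 in WT; 118 genes were chosen in both. The difference of the medians, each taken in the genotype other than the one used for choosing, was -0.41 with a spread of 0.07. Without the length trend it was -0.24. In these libraries the chosen genes as a group thus did not come down less in KO. From 12 to 24 h, 1438 genes were called in KO and 648 in WT, or 900 and 593 without the trend. Wider differences in the KO pair could also give a negative value, and single libraries cannot speak for the genotype. For chemokines the list median from 12 to 24 h was 0.20 in KO and -1.07 in WT as deposited, and -0.29 and -1.19 without the length trend; that contrast was not tested.

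Ccl2, Ccl7 and Ccl12 are neighbours on chromosome 11, and a change of the whole region could raise them together. Within 500 kb only 1 other gene was measured, Ccl8, itself a chemokine of the cluster, with a mean over 3 times of 1.29 (SD 0.93). With 1 gene, a regional change and a change of these chemokines by signalling cannot be told apart.

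The limma fit called 2 genes for the real split of the 6 libraries into WT and KO. Of the 10 ways to split them, 3 gave as many, and the highest other split gave 6; 10 splits are too few for a share under 0.05. With the length trend removed the real split again called 2 and the highest other split 0. In only 4 splits does each side hold 1 library of each time, as the fit requires for all times to count; of these the real split called 2 and the highest other 0, both ways.

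The KO 24 h library differed from the rest in more than inflammation. Histone transcripts (median 1.39 over 6 genes) and Malat1 (225.7 FPKM, against 27.6 to 100.6 in the others) were high, and long transcripts were low. Ifnb1 lay at 0.19, 1.52 and 1.85 FPKM in KO and at 0, 0.70 and 1.19 in WT at 0, 12 and 24 h, near the floor of the table. Csf1 was called higher at each time, the gene of the same factor the cells were grown with.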
